A study of Homo sapiens with 2 samples.

How the data were processed

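Total RNA from HCT15 cells with stable lentiviral shRNA was compared between 1 LYAR-shRNA sample and 1 scramble-shRNA sample, which the labels assign by their shRNA. Per the labels' protocols, hairpins were expressed from a lentiviral vector packaged in 293T cells, and infected cells were sorted on GFP fluorescence. RNA was reverse transcribed with oligo dT primers, labelled with Cy3, hybridised to Roche NimbleGen human expression arrays and scanned on a GenePix scanner, again per the labels' protocols. The labels mention more than 1 LYAR hairpin and do not say in words which one this sample carried.

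The authors' deposited values are intensities on a linear scale, summarised per probe set by RMA, per the submitters' processing notes. The RMA version, its background and normalization settings, and which arrays were normalized together are not given in the sources used here. Per the file headers, 45031 of the 45033 probe sets were summarised from 3 probes, 1 from 2 probes and 1 from 1 probe, and positions are given in the hg18 build. Where RMA brings the probes of both arrays to a shared distribution, the typical gene is equal by construction, and a shift of most genes in one direction would not be visible. The deposited files hold a further column, a score with the name of a standard error and no stated scale. It rose with intensity (Spearman 0.936 and 0.923 across probe sets), so it was not used as an error. A deposited series table of intensities held 22639 of the probe sets, equal to the array values within 0.0403. Its lowest value on the brighter array was 100.06, yet 2975 probe sets at or above that value were absent from it, and the filter behind it is not stated in the sources used here. It was used as an alternative only.

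Gene IDs per the file headers named 42947 probe sets, and 2086 had none. Symbols were updated through the gene ID with the RefSeq gene table of assembly GRCh38.p14, which held 38916 of these probe sets (90.6%), and the files' own symbol was kept otherwise. No coordinate was taken from that table. A gene's value was the mean log2 intensity of its probe sets on each array, giving 23619 genes, 11759 of them with 1 probe set. The difference was LYAR shRNA minus scramble shRNA with no pseudocount. Counts covered the 12682 genes whose value on the brighter array was at or above the median of all genes' mean, an intensity of 105.9. Their median difference was 0.05 and their SD 0.60. A gene dim on 1 array can pass through the other alone, and passing then fixes the sign of its difference. The random control probes, 5000 per array, had an intensity of 30.3 on the LYAR-shRNA array and 32.7 on the scramble-shRNA array. A value under 2 times that intensity was treated as a bound, with the fold taken against 2 times the random intensity and written as at least N-fold. It was computed for each probe set of the gene, and the smallest is given. Ranks and counts used the measured intensities, so genes with a bound have no known order, and a gene's mean can rest on probe sets near the random probes. The bound rule, and the choice to leave probe sets without a gene ID out of the genes, were made after a look at the data.

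With 1 array per group no test was made and no p-value is given. Genes were counted by size, at 2-fold or more. Each gene list was summarised by its median difference over measured members and by the percentile of that median among 10000 random lists of the same size, drawn from 20 bins of mean expression. Members that passed the filter were counted at 2-fold or more. The design, the filter, the threshold, most of the alternatives, the rule for named genes and 26 gene lists were fixed before the data were examined. The lists covered fatty acid synthesis, oxidation, and uptake and storage, cholesterol synthesis, ribosome biogenesis, ribosomal proteins, actin and migration, epithelial junctions, mesenchymal genes, S phase, and G2 and mitosis. They also covered the interferon response, NF-kB, p53, stress responses, hypoxia and glycolysis, NRF2, Wnt targets, colon differentiation and globins. The rest covered fibroblast, immune, endothelial, and neuronal or embryonic kidney markers, handling of cells or RNA, and reference genes. A further 3 lists (blood cells, hypoxia, sterols) were written after the first results and before their own members were looked at.

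Named genes were LYAR, FSCN1 and LGALS1, then the 12 largest differences in each direction among genes that passed the filter and had a symbol that was not a placeholder. Within each list, up to 2 passing members with the largest difference in each direction were named, or up to 4 in the fatty acid lists. The rule passed over 3 placeholder symbols at the higher end and 5 at the lower end. It gave 124 genes, and others are said to have been named after their values were seen. A few genes that the rule gave, or that counts include, are not reported here by name.

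Alternatives were the brightest probe set of each gene, the series value table, centring on the median, removal of a lowess trend on level, quantile normalization of the arrays, no filter or a filter at the 75th percentile, a pseudocount of 16 and a threshold of 1.5-fold. Chosen after seeing the data were the removal of trends on level, local gene density (genes within 500 kb) and gene span, a restriction to genes whose 2 or more probe sets all pointed the same way, and the counting of probe sets without a gene ID as genes. A value was taken to have moved when it changed by at least the pooled SD between probe sets of a gene (0.463), by at least the SD of matched random lists for a list median, or by over 1.5 times for a count. Percentiles of lists are given for 8 settings, the main one included. Centring subtracts a constant and cannot change a percentile, so in counts of settings it repeats the main result. An alternative on single probes was not run, because the values were already summarised per probe set.

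The steps were tested on simulated data built from these arrays, with 50 genes shifted by each size among 12682. Of genes shifted by -2, 96% were counted at 2-fold or more in that direction, and 100% of those shifted by 2. At -1 and 1, the edge of the threshold, the shares were 36% and 70%, and 6.74% of genes with no planted shift were counted in either direction, because the simulation shuffled the real differences among genes of similar level. Simulated lists of 30 genes were drawn from the 12682 that passed the filter and set against random lists from all 23619. Of the simulated lists, 3% fell outside the 95% range with no shift, 54% with a shift of 0.2 and 99% with a shift of 0.4. The shuffle removed correlation between genes, so the 3% does not cover lists whose genes vary together. Lists with many dim members were not simulated. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.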

Results

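Gene expression was measured in HCT15 cells, an established human colorectal cancer line, that stably carried either an shRNA against LYAR or a scramble control shRNA. LYAR is a zinc-finger protein of the nucleolus, and the series title ties it to FSCN1 and to fatty acid metabolism in colorectal cancer. Each condition was hybridised to 1 single-colour oligonucleotide array, so every difference below compares 2 arrays and has no replicate check. Of the 45033 probe sets on each array, 63.0% exceeded 2 times the intensity of the random control probes on the LYAR-shRNA array and 61.3% on the scramble-shRNA array. Median probe-set intensity was 120.7 and 116.1, with quartiles of 40.6 to 757 and 41.4 to 734. Across probe sets the log2 intensities of the arrays correlated with a Pearson r of 0.966, where probe sets are not independent replicates. With 1 array per group, the number of arrays sets the precision, and the pooled SD between probe sets of the same gene, 0.463 on the log2 scale, is the only spread that can be given. Differences are log2 of the LYAR-shRNA intensity minus log2 of the scramble-shRNA intensity.

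LYAR, the targeted gene, had an intensity of 1036 on the LYAR-shRNA array and 1925 on the scramble-shRNA array. This was a difference of -0.89, or 53.8% of the control value, from 1 probe set annotated in hg18 on chromosome 4 from 4320336 to 4342744. The direction went with the labels. Among the 12682 genes that passed the intensity filter, 4.82% lay further toward lower values than LYAR. FSCN1, which encodes the actin-bundling protein fascin, was 3.04-fold lower on the LYAR-shRNA array, with 241 against 733 and a difference of -1.61. Its probe sets, on chromosome 7 between 5598979 and 5612812 in hg18, gave -2.11 and -1.10. LGALS1, which encodes galectin-1, measured 5300 and 5778, a difference of -0.12 that was smaller than the spread between probe sets. The questions the comparison addresses are which genes differ when LYAR is reduced, and whether FSCN1 and genes of fatty acid metabolism are among them.

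The largest measured difference in the direction of the LYAR-shRNA array belonged to ANKRD37, a gene induced by hypoxia, at 2094 against 186 and a difference of 3.49. SP5, a transcription factor gene induced by Wnt signalling, differed by 2.49. CXCL2, a neutrophil-attracting chemokine, was at least 2.57-fold higher, with 1 of its 2 probe sets near the random probes and the brighter one at 2.39. The other 9 of the 12 named genes at this end lay near the random probes on the scramble-shRNA array, so only a lower bound could be given. TRIB2, a pseudokinase gene, was at least 3.70-fold higher, RBP4, a retinol carrier, at least 5.43-fold and IGFBP3, an IGF-binding protein, at least 4.18-fold. STOX2 was at least 4.29-fold higher, ZSCAN5A at least 3.90-fold and FXYD6 at least 3.60-fold. TSPAN7 was at least 2.95-fold higher and CYP11A1, the side-chain cleavage enzyme of steroid synthesis, at least 2.06-fold. The gene listed as GOLGA8F, a member of a multi-copy family whose gene ID is absent from the current RefSeq table, was at least 3.77-fold higher and is uncertain for that reason.

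At the other end stood DKK1, a secreted Wnt antagonist, with 718 on the LYAR-shRNA array against 8338 on the scramble-shRNA array, a difference of -3.54. Both of its probe sets gave values from -3.60 to -3.47. Many of the remaining genes at this end are known from blood rather than from colon epithelium. IGKC, the constant region of the immunoglobulin kappa chain, was at least 1.34-fold lower over its 19 probe sets, of which 9 lay near the random probes on the LYAR-shRNA array and the others gave -3.89 to -2.92. IGKV1-5, a kappa variable segment, was at least 8.22-fold lower, and immunoglobulin segments can share probes with related segments. CD79A, a B-cell receptor subunit, was at least 5.13-fold lower and IGHM at least 2.30-fold lower on the LYAR-shRNA array. HBB and HBD, which encode near-identical beta-type globin chains, were at least 3.87-fold and at least 3.06-fold lower. SIPA1, a Rap GTPase-activating protein, was at least 4.78-fold lower. The homeobox genes HOXC10 and HOXA2 were at least 4.09-fold and at least 2.80-fold lower. The choline transporter-like gene SLC44A4 was at least 2.68-fold lower and P2RY8, a P2Y receptor family member by name, at least 3.14-fold. LOC646190, whose placeholder name the naming rule passed over, was at least 9.91-fold lower and was named after its value was seen.

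**Figure D1:**
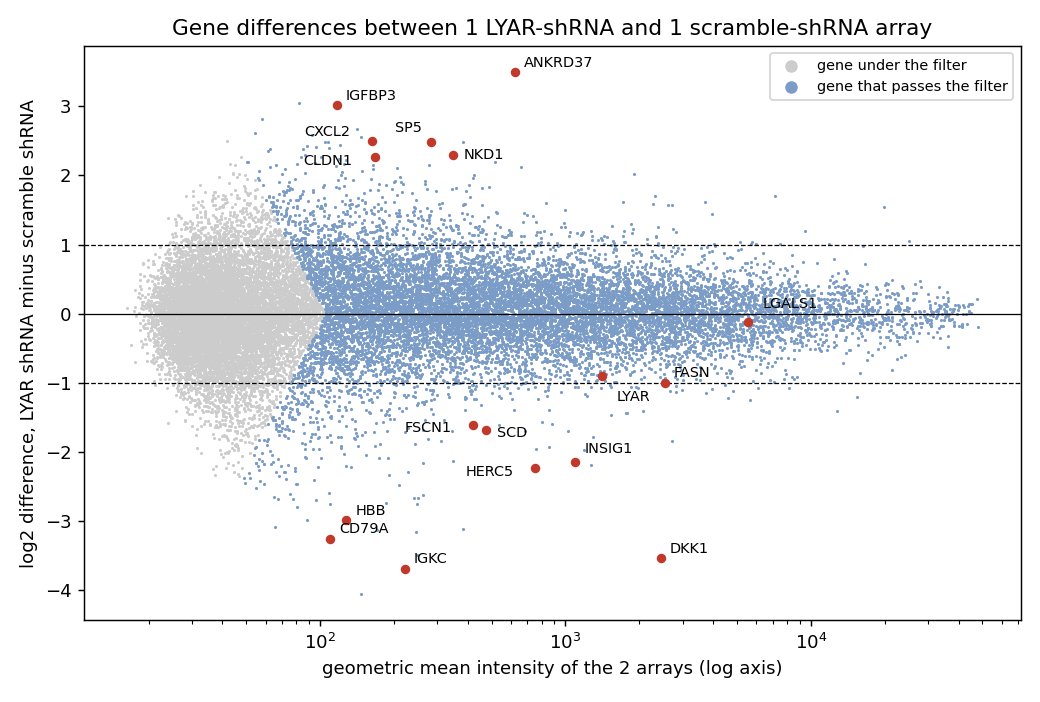
Each point is 1 gene, with the geometric mean intensity of the arrays on a log axis and the log2 difference (LYAR shRNA minus scramble shRNA) on the vertical axis. Grey points failed the intensity filter, blue points passed it, dashed lines mark 2-fold, and red points are named genes, from ANKRD37 at 3.49 to IGKC at -3.68 by measured intensities.

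In all, 642 of the 12682 genes that passed the filter (5.06%) were at least 2-fold higher on the LYAR-shRNA array, and 452 (3.56%) were at least 2-fold lower. At 4-fold the counts were 49 higher and 75 lower. These are counts by size, with no test. Most of them came from weak signals, since 446 of the higher and 337 of the lower genes lay among the 4227 dimmest genes that passed, against 49 and 33 among the 4228 brightest. The pooled SD between probe sets of a gene was 0.654 in the dimmest group and 0.232 in the brightest. Where a gene at or past 2-fold had 2 or more probe sets, all of them pointed its way in 258 of 263 higher genes and 129 of 137 lower genes. Among all 7134 passing genes with 2 or more probe sets, this held for 2504 genes with a higher and 1840 with a lower mean. Selection on the mean of the probe sets favours such agreement, and the probe sets read the same arrays, so it does not count as a replicate.

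Genes of fatty acid synthesis included several of the clearer lower values. SCD, the stearoyl-CoA desaturase, differed by -1.68 (265 against 851). ACSL4, a long-chain acyl-CoA synthetase with a preference for arachidonic acid, differed by -1.16, and ACSS2, which makes acetyl-CoA from acetate, by -1.13. FASN, the fatty acid synthase itself, stood at 1796 against 3589, just under 2-fold at -0.999 and past it with centring, the lowess trend or quantile normalization, and was on chromosome 17 from 77629502 to 77649395. In the opposite direction the desaturase family gene FADS3 differed by 0.96, the elongase gene ELOVL7 by 0.69, the acyl-CoA synthetase gene ACSL5 by 0.65 and ELOVL6 by 0.39. Of the 36 listed genes, 29 passed the filter, with 3 at least 2-fold lower, 0 at least 2-fold higher and 26 under 2-fold. The median over all 36 was -0.07, at the 12.5th percentile of matched random lists. The mean was -0.16, while the median of the 29 passing genes was 0.01 and that of all measured genes turned to 0.09 with the brightest probe set or the series value table, so the list as a whole had no settled direction.

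Fatty acid oxidation genes leaned toward the LYAR-shRNA array without standing apart from random lists. EHHADH, the peroxisomal bifunctional enzyme, differed by 1.12, though its probe sets gave 0.22 and 2.01, the latter near the random probes on the scramble-shRNA array. ETFDH, which passes electrons from acyl-CoA dehydrogenases to ubiquinone, differed by 0.99. DECR1, the mitochondrial dienoyl-CoA reductase, differed by 0.93 and HSD17B4, a peroxisomal enzyme, by 0.81. ACADSB, ETFB and ACADS lay at -0.17, -0.10 and -0.09, and each had probe sets of both signs. Of 30 passing genes 23 were higher and 7 lower, with 1 at least 2-fold higher and 0 at least 2-fold lower. The median over the 36 measured genes was 0.15, at the 93.2nd percentile.

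For uptake and storage of fatty acids the members went both ways. PNPLA3, a lipid droplet protein, differed by 1.27 and FABP3, a fatty acid binding protein, was at least 1.06-fold higher. SLC27A2, a fatty acid transport protein, differed by 0.73. PPARG, a lipid-sensing nuclear receptor, had a mean of 0.95 that rests on a probe set near the random probes, while the other probe sets gave -0.04 to 0.83. The acyltransferase gene AGPAT2 differed by -0.86, and PNPLA2, which encodes adipose triglyceride lipase, by -0.70. DGAT1, which makes triglyceride, differed by -0.66 and LIPE, hormone-sensitive lipase, by -0.57. Of 25 passing genes, 2 were at least 2-fold higher by measured intensities, 0 were at least 2-fold lower and 23 were under 2-fold. The median was 0.01, at the 39.1st percentile, and the mean was -0.01.

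Cholesterol synthesis and uptake genes were lower as a group on the LYAR-shRNA array. INSIG1, a sterol sensor of the endoplasmic reticulum, differed by -2.14 (523 against 2304). The mevalonate pathway gene MVD, named after its value was seen, differed by -1.12. PMVK and SC5D, which act early and late in the pathway, were the members with the highest differences, at 0.48 each. Of the 24 passing genes, 20 were lower and 4 higher, with 4 at least 2-fold lower and 0 at least 2-fold higher. The median of the 25 measured genes was -0.44, below all 10000 matched random lists, whose 95% range was -0.16 to 0.21.

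**Figure D2:**
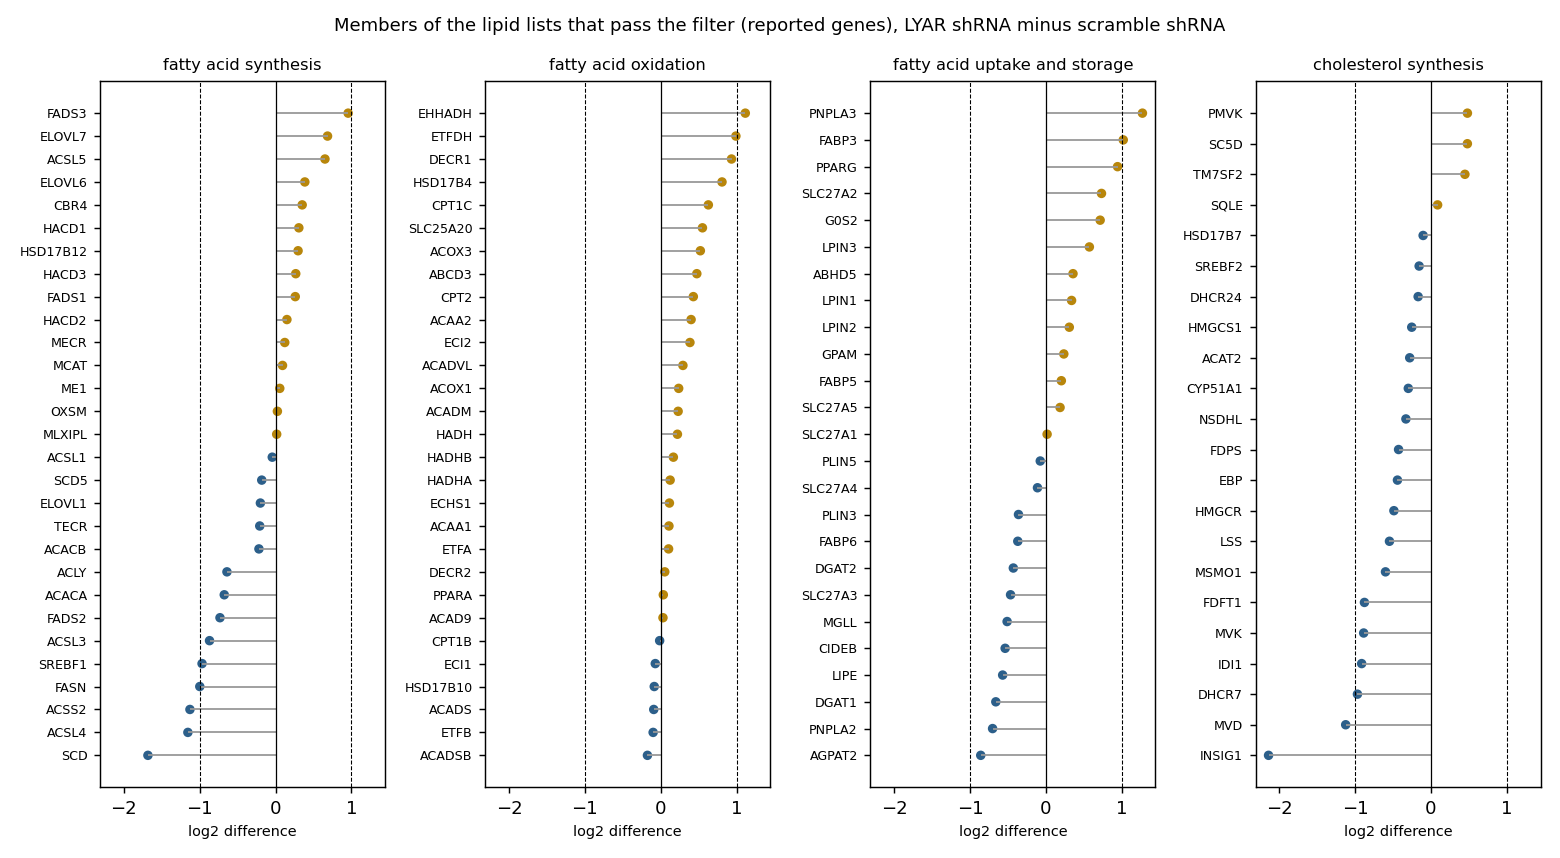
Each panel plots the log2 difference (LYAR shRNA minus scramble shRNA) of members of 1 lipid list that passed the filter, sorted by value, with dashed lines at 2-fold. In the cholesterol panel most genes lie below 0, with INSIG1 lowest at -2.14, and in the fatty acid synthesis panel SCD lies lowest at -1.68.

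Hypoxia and glycolysis genes were higher on the LYAR-shRNA array, with 27 of 32 above 0, 10 at least 2-fold higher and 1 at least 2-fold lower. ANKRD37 led them, followed by EGLN3, an oxygen-sensing prolyl hydroxylase that is itself induced by hypoxia, at 1.88. NDRG1 and CA9, named after their values were seen, differed by 1.71 and 1.61. Against the group, the aldolase gene ALDOC was at least 2.05-fold lower. PFKM, muscle phosphofructokinase, had a mean of -0.47 that rests on a probe set near the random probes, while the others gave -0.32 to 0.04. The list median was 0.44, above all 10000 matched random lists.

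Wnt target genes were also higher as a group, while DKK1 went the other way. Beside SP5, the Wnt feedback gene NKD1 differed by 2.29 (771 against 158). LEF1, AXIN2 and APCDD1, named after their values were seen, differed by 1.35, 1.26 and 1.02, and CD44 by 1.94, or by 1.29 in its brightest probe set. MSI1, an RNA-binding protein of progenitor cells, differed by -0.38. Among the 20 genes that passed, 6 were at least 2-fold higher, 1 was at least 2-fold lower and 15 were above 0. The count of 6 was 5 with centring, the lowess trend, quantile normalization, the pseudocount or trends removed, where APCDD1 fell under 2-fold. The median over 25 measured genes was 0.68, above all 10000 matched random lists.

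Inflammatory genes regulated by NF-kB had a median of 0.27, at the 98.9th percentile. Of 17 that passed, 5 were at least 2-fold higher, namely CXCL2, CXCL1 at 1.62, CXCL8 and LCN2 at 1.55 and 1.04, and CXCL3, which was at least 2.36-fold higher, the last 3 named after their values were seen. LTB, which encodes lymphotoxin beta, differed by -1.08, or by -0.84 in its brighter probe set, and the NF-kB subunit gene RELB by -0.85. With the series value table the list stood at the 91.3rd percentile and its passing genes alone at the 95.2nd, both inside the 95% range. Interferon response genes had a median of -0.13, at the 3.78th percentile, within the 95% range, but fell below that range in 3 of 8 settings, with the series value table, at the 2.27th percentile with the lowess trend removed and at the 2.21st with quantile normalization, as did the passing genes alone, at the 2.16th. Among them HERC5, an ISG15 ligase, differed by -2.24 (345 against 1626). OASL, an oligoadenylate synthetase-like gene, had a mean of -1.76 that rests on a probe set near the random probes on the LYAR-shRNA array. Its brighter probe set gave -0.86. IFI44 was at least 1.69-fold higher and the helicase gene DDX60 at least 1.87-fold. Of 30 interferon genes that passed, by measured intensities 1 was at least 2-fold higher and 2 were at least 2-fold lower.

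For the integrated stress and unfolded protein responses the median was 0.14, at the 92.9th percentile. PSAT1, of serine synthesis, differed by 0.90 and the lipoprotein receptor gene VLDLR by 0.79, whereas DNAJB9, in its brighter probe set, and HERPUD1, both of the endoplasmic reticulum stress response, differed by -1.27 and -1.10. Of 27 that passed, 0 were at least 2-fold higher and 2 at least 2-fold lower. The NRF2 and antioxidant genes had a median of -0.11, at the 7.49th percentile, and 0 of 23 passing genes reached 2-fold either way. The passing genes alone had a median of -0.19 at the 0.81st percentile, and the whole list lay below the 95% range with the brightest probe set (-0.24) and the series value table (-0.21). ABCC3, a drug efflux transporter, differed by 0.53 and catalase (CAT) by 0.46, against -0.93 for OSGIN1. With p53 targets the median was 0.01, at the 42.5th percentile, and 0 of 19 reached 2-fold. DDB2 and TP53I3 differed by 0.88 and 0.45, and the apoptosis genes BBC3 and BAX by -0.58 and -0.56.

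Ribosomal protein genes lay slightly higher on the LYAR-shRNA array, with 48 of 55 above 0, 0 past 2-fold and a median of 0.13 at the 99.8th percentile. Grouped by symbol stem, after the lists were seen, the median was 0.16 for RPL genes and 0.05 for RPS genes. RPS23 differed by 0.48. The mean of 0.59 for RPS3 rests on a probe set near the random probes on the scramble-shRNA array, at 1.63, while its bright probe sets gave 0.03 and 0.12. RPS2 differed by -0.16. Many of these genes have processed pseudogenes that probes can share. Ribosome biogenesis genes, the class closest to the nucleolar role of LYAR, had a median of 0.05 at the 62.3rd percentile, and the median fell below 0 in 4 of 8 settings (centring, the lowess trend removed, quantile normalization and trends removed), to -0.02 at the lowest. NOP56, a box C/D snoRNP protein, differed by 1.01 and was the 1 gene of 49 past 2-fold. The assembly factor gene RRS1 differed by 0.75, and UTP20 and NOL6 of the small-subunit processome by -0.82 and -0.73.

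As groups, genes of DNA replication were higher and genes of mitosis lower. Of 29 S-phase genes that passed, 23 were above 0, with a median of 0.24 over 30 measured genes at the 99.8th percentile. MCM6, a subunit of the replicative helicase, differed by 1.11 and the cyclin gene CCNE2 by 0.90, while CDC45 and the licensing factor gene CDT1 differed by -0.41 and -0.29. MCM6 was the 1 gene of this list past 2-fold. For G2 and mitosis genes 22 of 32 were below 0, with a median of -0.17 at the 1.06th percentile. With the series value table that percentile was 3.45, inside the 95% range. DLGAP5, a spindle protein and the 1 gene past 2-fold here, differed by -1.23 and ANLN, of cytokinesis, by -0.82. MKI67 and the centromeric histone gene CENPA went the other way, at 0.78 and 0.56.

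Actin and migration genes, the list that holds FSCN1, did not stand apart as a group. The median was -0.01 at the 25.8th percentile and the mean 0.06, with 3 of 50 passing genes at least 2-fold higher and 2 at least 2-fold lower. Besides FSCN1 the lower gene was TPM2, a tropomyosin, at -1.05, or -0.75 in its brightest probe set. The higher genes were the myosin light chain gene MYL9 at 1.39, the membrane-cytoskeleton linker gene RDX at 1.35, and TAGLN2 at 1.06, which was named after its value was seen. In the brighter of the MYL9 probe sets the difference was 0.79, and in the brightest of TAGLN2 it was 0.96, both under 2-fold. The other MYL9 probe set lay near the random probes on the scramble-shRNA array, so MYL9 is counted by measured intensities only. Epithelial junction genes had a median of -0.07 at the 16.1st percentile and a mean of 0.08. The tight junction gene CLDN1 was at least 3.11-fold higher, with its brighter probe set at 2.41, and others differed less, CLDN2 by 0.93, the repressor gene OVOL1 by -0.94 and the membrane protease gene ST14 by -0.53. CLDN1 was the 1 gene of 28 past 2-fold.

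Mesenchymal genes had a median of 0.05 at the 64.3rd percentile, which rose to 0.18 with the brightest probe set and turned to -0.16 with the series value table, so its direction was not settled. Of 12 that passed, the integrin gene ITGA5 differed by 1.02, TGFB2 was at least 1.64-fold higher, SNAI1, an EMT transcription factor, differed by -1.15 and FOXC2 by -0.23. By measured intensities 2 were at least 2-fold higher and 1 at least 2-fold lower. For colon differentiation genes the median was 0.04 at the 61.0th percentile, and 0 of the 13 that passed reached 2-fold. The mucin genes MUC13 and MUC2 differed by 0.75 and -0.85, PHGR1 by 0.70 and TFF1, a trefoil peptide, by -0.41.

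The globin and immune marker lists were lower on the LYAR-shRNA array, alongside the groups above. The globin list had a median of -1.70, below all 10000 random lists, and its 4 passing genes, HBB, HBD, HBA1 and HBA2, were each at least 2-fold lower by measured intensities. HBA1 and HBA2 have nearly the same sequence and cannot be told apart by probes that both match. Of 7 immune marker genes that passed, all were lower and 4 at least 2-fold by measured intensities, namely CD79A, CD68 at -1.88, NKG7 at -1.28 and CD3E, which was at least 1.75-fold lower, the last 2 named after their values were seen. The median over 16 measured immune markers was -0.42, at the 0.67th percentile. Genes such as HBB and CD79A passed the filter only through the scramble-shRNA array, which fixed their direction. Agreement among the passing genes of these lists is therefore partly by selection, while the medians cover all measured members. Endothelial markers had a median of -0.07 at the 34.6th percentile, with ROBO4 at least 2.23-fold lower and ESAM at -0.79 as the 2 that passed. Fibroblast markers had a median of 0.02 and a mean of -0.03, at the 57.2nd percentile, with COL1A1, at 0.42 in its brighter probe set, and ACTA2 at 0.49 as the 2 that passed. In the list for the packaging line and for neurons only TUBB3 passed, at -0.53, and the median of 12 mostly dim genes was 0.18, with a mean of -0.04, at the 88.9th percentile.

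Heat-shock and immediate-early genes had a median of -0.37 at the 0.06th percentile, with 11 of 15 below 0. They were listed as a sign of handling, of the cells or of the RNA, and are not a direct measure of RNA quality. ZFP36, an mRNA decay factor induced early, differed by -1.18 and the heat-shock gene HSPA6 by -1.09, though its brighter probe set gave -0.45. JUN was at least 2.12-fold higher, in the opposite direction, and DUSP1 differed by 0.15. The 17 reference genes often used for qPCR had a median of -0.003 and a mean of 0.04 at the 41.9th percentile, and 0 reached 2-fold. GUSB and YWHAZ differed by 0.60 and 0.51, SDHA by -0.86, and POLR2A by -0.28 with probe sets of both signs.

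**Figure D3:**
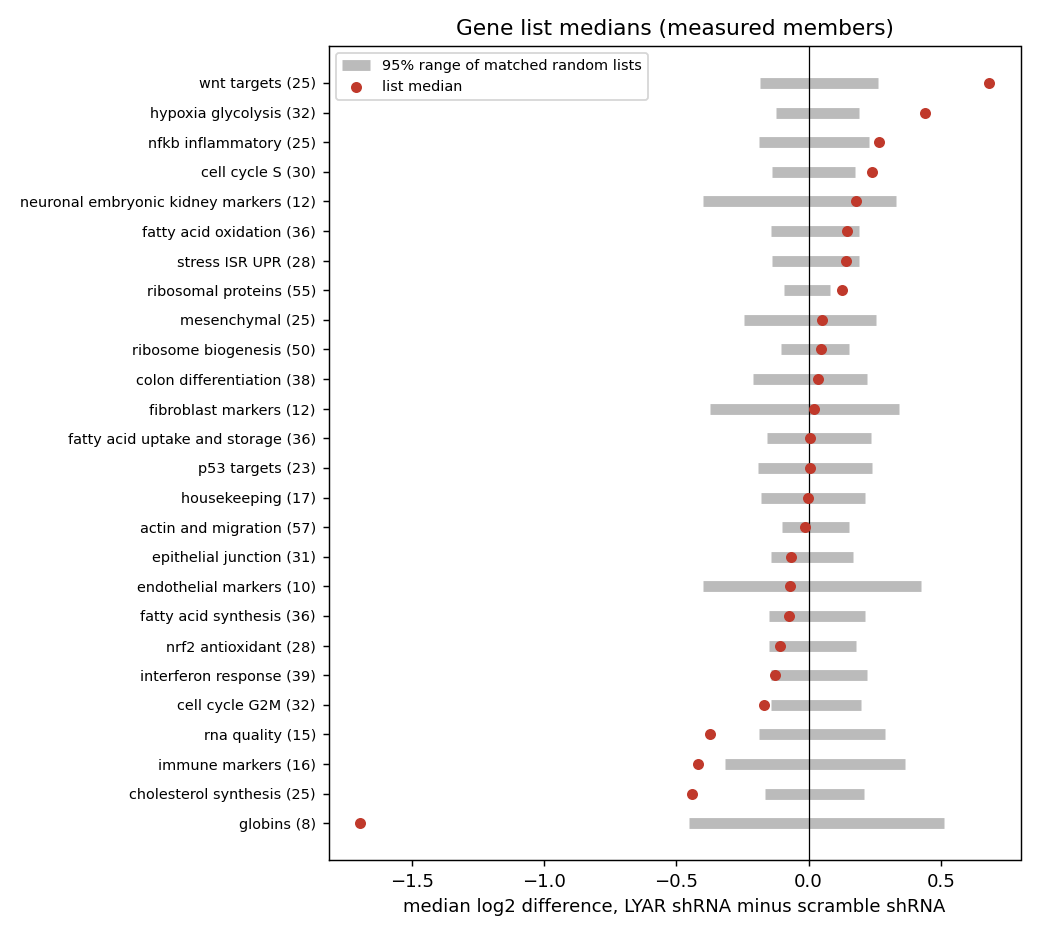
Red points are the median log2 difference (LYAR shRNA minus scramble shRNA) of each gene list over its measured members, whose number stands in parentheses. Grey bars are the 95% range of 10000 random lists matched on mean expression, and 5 lists lie above their bar, 5 below it and 16 within it.

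Of the 26 lists, 5 lay above the 95% range of random lists and 5 below it, where 1.3 would be expected outside by chance for independent lists. The percentiles describe these arrays and are not tests of the knockdown. Lists that share genes are not independent of each other. Random lists draw genes singly and do not carry correlation between the genes of a list, so 1.3 is not a chance count for genes that vary together. All lists were compared on the same arrays, on which the heat-shock and immediate-early list and the blood lists also differed, so no group, including hypoxia, Wnt and cell-cycle genes, was separated from those differences. Medians near 0, all of lists inside the 95% range, often changed sign in another setting.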

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

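Of the tests in this part, those on the knockdown as the source of the blood transcripts and on culture density were chosen only after the result was seen. The trends on gene density and span and the additional lists were also chosen after seeing the data, before their own values were known.

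Differences of 2-fold or more also appeared among the probe sets left out of the genes. Of the 2086 probe sets without a gene ID, 799 passed the intensity filter, and 60 were at least 2-fold higher and 105 at least 2-fold lower on the LYAR-shRNA array. These are counts by size with no test. They cover single probe sets, so they are not like the counts of genes, whose values are means over probe sets.

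Blood transcripts on the scramble-shRNA array stood out because the cells were a colorectal cancer line sorted on GFP. Such a sort would leave out uninfected blood cells. HBB, CD79A and the mean of IGHM lay near the random probes on the LYAR-shRNA array, against 361, 339 and 505 on the other. For IGHM, 3 of its 5 probe sets lay near the random probes, while the others read 124 and 117 on the LYAR-shRNA array. A trend with intensity left by the normalization is argued against, since the random lists were matched on level and the globin median lay below all of them. With that trend removed the median was -1.71, still below all matched random lists, which adds little because of the matching. RNA of blood cells, through a mixed sample or spill from another array of the slide, could be a source. A separate list of 32 blood genes had a median of -0.20 at the 5.34th percentile, inside the 95% range of -0.24 to 0.26, which is the outcome written beforehand as counting against this source, though over the alternatives its percentile ran from 0 (series value table, 7 genes, median -1.06) to 30.4 (trends on level, gene density and gene span removed, median -0.04). The main value of -0.20 missed the bound by less than the SD of random lists (0.126), and 23 of the 32 genes were dim. The 9 that passed had a median of -0.84, with 6 lower and 3 higher. The filter took the brighter array, so dim genes such as HLA-DRA and CTSG passed through 1 array alone, which fixed their direction. The passing genes are thus no separate support beside the median over all 32. By measured intensities 4 were at least 2-fold lower and 2 at least 2-fold higher. Members of this list are named after their values were seen. Among the lower genes were CD7 (240 against 634), ARHGDIB (103 against 223) and CD74 (354 against 632), by measured intensities. HLA-DRA and CD37 were at least 1.14-fold and at least 1.08-fold lower. The 3 others were CORO1A at 0.01, CTSG, at least 2.00-fold higher, and the B-cell marker CD22 at 1.20 (151 against 65.6). CD22 goes only weakly against a blood source, since its value on the scramble-shRNA array was close to 2 times the random probes. That source stays open, as does the knockdown itself (globin median -1.70), which 1 array per group cannot separate from it.

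Hypoxia and glycolysis genes on the LYAR-shRNA array had a median of 0.48, above all matched random lists, after trends on level, gene density and gene span were removed. These trends, used as stand-ins for GC content and gene length, thus did not hold the whole of the pattern. They were small beside the list median, with an SD of 0.079 across genes, so their removal could hardly have changed the outcome. Probe GC content and transcript length were not measured, so a bias of either stays open. A separate list of 28 hypoxia genes, whose members had not been looked at, had a median of 0.30 at the 99.49th percentile, consistent with a wider hypoxia response. It lay outside the 95% range in 6 of 8 settings, and with those trends removed its median fell to 0.19 at the 95.8th percentile, inside the range, so its support depends on the processing. SLC16A3 at -0.88 went against it. The knockdown and a denser or less aerated culture cannot be told apart as its source with 1 culture per group (list median 0.44). Handling of cells or RNA (heat-shock and immediate-early list at -0.37) or a mixed sample (blood transcripts) was not separated from such a response either.

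Cholesterol genes had a median of -0.37, at the 0.01th percentile, after the same trends were removed, so those trends did not hold the whole of the pattern. The trends were again small beside the list median. A bias of probe GC content or transcript length stays open here too, since neither was measured. A separate list of 16 genes tied to sterol regulation had a median of -0.22 at the 2.08th percentile, just past the bound of the 95% range at -0.21. A wider fall of SREBP2 targets has only weak support from this, since the list was outside the range in 4 of 8 settings (percentiles from 1.62 to 15.4), and the 15 genes that passed, 7 higher and 8 lower with 0 past 2-fold, had a median of -0.19 at the 4.09th percentile, inside the range. The knockdown and the state of the culture both stay open. The heat-shock and immediate-early list (-0.37) and the blood transcripts differed between the same arrays. Handling of cells or RNA, or a mixed sample, was therefore not separated from the pattern.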

How the results depend on the processing

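Of the alternatives, the trends on level, gene density and span, the genes with concordant probe sets and the counting of unnamed probe sets were chosen after seeing the data. LYAR was lower under every alternative that changed values, from -0.96 to -0.88, and FSCN1 from -1.67 to -1.10, the last with its brightest probe set alone. Among the named genes and the lists, no called value turned its sign. Cholesterol, ribosomal protein, S-phase, hypoxia, Wnt, globin, immune, and heat-shock and immediate-early lists stayed outside the 95% range in all 8 settings. The G2 and NF-kB lists did so in 7 of 8. These counts include the main setting and centring, which has the same percentiles by construction. With the brightest probe set, list medians moved to 0.0914 for fatty acid synthesis, 0.18 for mesenchymal genes, -0.24 for NRF2, 0.51 for Wnt targets, -0.77 for immune, -0.36 for endothelial and 0.13 for reference genes. With the series value table they moved to 0.0916 for fatty acid synthesis, -0.16 for mesenchymal genes, -0.21 for NRF2, 0.29 for colon differentiation, 0.64 for fibroblast, -0.98 for immune, -0.79 for endothelial and -0.53 for neuronal and kidney markers, where that table held fewer dim members, 4 for immune, 2 for fibroblast and 1 each for endothelial, for neuronal and kidney, and for globins, whose value there is HBA2 alone. NRF2 genes then fell outside the 95% range, at the 0.26th and 0.35th percentiles. Ribosomal proteins moved to 0.0735 with centring and 0.19 with trends removed, epithelial genes to 0.0765 with trends removed, ribosome biogenesis to -0.0244 with quantile normalization and globins to -1.40 with the pseudocount. Among named genes past 2-fold, 6 of 58 were under it with the brightest probe set: FABP3, HSPA6, LTB, MYL9, OASL and TPM2. FABP3, ITGA5, NOP56, EHHADH, HERPUD1, LTB, MYL9 or TPM2 were under it in at least 1 other setting, and FASN was past it with centring, the lowess trend or quantile normalization. Among genes named after their values were seen, TAGLN2 was under 2-fold with the brightest probe set, APCDD1 with centring, the lowess trend, quantile normalization, the pseudocount or trends removed, LCN2 with centring, DNAJB5 with the brightest probe set, the series value table or the pseudocount, and DNAJB4 with the pseudocount, while IRF9 was past it with centring, the lowess trend or quantile normalization and IRF5 with the brightest probe set. Counts moved to 1167 higher and 1025 lower with no filter, 136 and 92 with the stricter filter, 1903 and 1393 at 1.5-fold, and 258 and 129 for concordant probe sets, by construction. Centring gave 559 and 533, the lowess trend 542 and 533, quantile normalization 557 and 542, and unnamed probe sets as genes 767 and 611. The higher share of called genes was 58.7% and at its lowest 50.4%, with the lowess trend, so the excess of higher over lower genes rests on the scaling. Signal over background limits the rest: 188 of the 642 higher and 182 of the 452 lower genes lay near the random probes on the dimmer array, where a fold is a bound. Beyond what the text gives by construction, the cause of these moves was not tested. No paired analysis was possible because each group has 1 array. The alternative on single probes was not run.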

Other observations

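The tests in this part were chosen after the gene lists had been seen, and the families are exploratory. Symbols that share a stem were grouped into 161 families of at least 8 genes that passed the filter, and 7 families fell outside the 99% range of matched random lists. By chance 1.61 would be expected if genes varied independently. Members of a family can share probes or vary together, which the random lists do not carry, so 1.61 is not a chance count for such families.

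Keratin genes were among the families outside that range. Over 29 keratins the median was -0.33 at the 0.01th percentile, with 23 lower and 5 at least 2-fold lower. KRT13 differed by -2.33 and KRT3 by -1.84, while KRT8, KRT18 and KRT19, the abundant keratins of simple epithelia, lay at -0.00, -0.08 and -0.10. With trends on level, gene density and span removed, the keratin median was -0.24 at the 0.565th percentile, inside the 99% range. Genes of the DNAJB co-chaperone family had a median of -0.57 over 10 genes, with DNAJB5 and DNAJB4 at -1.14 and -1.10, though the brightest probe set of DNAJB5 gave -0.45. Interferon regulatory factors had a median of -0.55 over 9 genes that share the IRF stem, with 0 of them past 2-fold. Among them IRF9 differed by -0.96, and IRF1 and IRF5 by -0.72 each. IRF1 and IRF9 are in the interferon response list above and DNAJB9 in the stress list, so neither family is a fully separate result. Olfactory receptors, mostly of dim signal, had a median of -0.53 over 27 genes. The FBXL and GOLGA families also lay low, at -0.51 and -0.48, and FBXL was inside the 99% range, at the 1.85th percentile, with those trends removed. Large-subunit ribosomal proteins, with the stem RPL, lay high, with a median of 0.16 and 45 of 51 above 0. Many of them are in the ribosomal protein list above, so this is not a separate result. Genes with the stem RPS had a median of 0.05 at the 76.5th percentile, with 29 higher and 16 lower.

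Differences between the arrays varied along the genome. The Spearman correlation across the 12682 genes between the difference and the number of genes within 500 kb was -0.206, outside the range of 1000 shuffles (-0.0166 to 0.0159), though genes are not independent replicates. The gene-rich chromosomes 16, 17, 19, 20 and 22 had a median difference of -0.04 and the gene-poor chromosomes 3, 4, 5, 6, 13 and 18 a median of 0.11. In the most gene-dense 10% of genes the median was -0.15 and in the least dense 10% it was 0.18. A GC bias between the arrays, with gene density as its stand-in, is a candidate explanation, but probe sequences were not used here and a biological difference that follows gene density was not tested. Trends on level, density and span together held 1.72% of the variance of the differences.

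Genes past 2-fold were often missing from the deposited series table. Of the 452 lower genes 42.0% had no probe set in it, and of the 642 higher genes 29.9%, against 3.50% of the genes under 2-fold. On the dimmer array, 182 of the lower and 188 of the higher genes were near the random probes.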
